A study of Mus musculus with 2 samples.

How the data were processed

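Droplet-based single-cell RNA sequencing measured 3 prime transcript tags in innate lymphoid cells (ILCs) of the small-intestinal lamina propria of C57BL/6 mice. Live CD45+ cells negative for lineage markers, CD3 and TCRβ and positive for CD90.2 and CD127 were sorted, and cells of 4 mice were pooled per genotype, giving 1 wild-type (WT) library and 1 library from mice deficient for Zfp36 (Zfp36_KO, called knockout here). Per the file headers and the labels, the authors ran Cell Ranger 3.1.0 against genome build mm10, and the deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. The tables list called cell barcodes only, so RNA outside cells could not be measured from empty droplets. The files hold 31053 features, of which 31011 matched GENCODE release M21 by identifier. That annotation gave coordinates and, for 20986 genes, 3 prime UTR sequences. The annotation release that the authors used is not stated.

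Barcodes with fewer than 500 genes or more than 10% mitochondrial UMIs were removed, as were doublets predicted by Scrublet in scanpy 1.11.5 for each library on its own. Counts were scaled to the cell total and log transformed, the 2000 most variable genes were taken, and 30 principal components were computed. A graph of 15 nearest neighbours with shared-neighbour weights was clustered by the Leiden algorithm (leidenalg 0.10.2, resolution 1, seed 0). Cytokine and effector genes, Zfp36, heat-shock, immediate-early, mitochondrial, ribosomal, antigen receptor and sex-linked genes were left out of the variable genes, so that these did not define the clusters. Other outcomes, such as interferon-stimulated, MHC class II and receptor genes and Ly6a, were not left out. A cluster took the name of the marker list with the most members detected in at least 10% of its cells at 2-fold or more of the level in all other cells, if at least 3 members passed. These marker lists held some of the genes left out of the variable genes, among them Areg, Il13, Gzma and Ccl5, so such genes could still help to name a cluster. ILC3-like clusters were divided into LTi-like and NCR+ by further marker lists, at 1.5-fold among ILC3-like cells. A cluster stayed unnamed when another list had more members than its own among its 10 most enriched genes, which left out cluster 5 (0 of ILC1/NK and 1 of ILC2, with 7 and 6 passing members), or when its median UMI count was under 1/3 of the library's with none of its own markers among those genes. It also stayed unnamed when 3 or more of the 10 belonged to a competing list. That part was set after the data had been seen, as was the alternative with cluster 5 counted as ILC1/NK-like.

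For each class with at least 100 cells in each library, UMIs were summed over cells and expressed as CPM, the usual scaling of a gene's count by the total UMIs of the class. The log2 ratio of knockout over WT CPM was given with an exact 95% interval from the split of UMIs between the libraries, for genes with at least 50 UMIs over both. A gene with 0 UMIs in 1 library was set to a floor of 3 counts and its ratio given as a bound. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals. For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. With 1 library per genotype there were no replicates, so no test was made between genotypes. All intervals cover counting error only, and not the spread between mice or the uneven distribution of a transcript over cells. Data were simulated from the summed ILC3-like counts (9508 genes) with Poisson counting error only, which checks the computation and not that uneven distribution. There, 95.6% of intervals of unchanged genes held the true ratio. Of genes set 2-fold apart, 92.0% had an interval excluding 0 in the right direction.

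The median for each of 18 gene lists was set against 10000 random lists of the same size matched on mean expression. A percentile under 2.5 or over 97.5 was called apart from random lists. In the simulated data, 7 of 100 lists of 20 unchanged genes fell outside these limits. A list member was counted as higher or lower when it had at least 20 UMIs and a ratio of 1.5-fold or more, and named only if its interval also excluded 0. The lists were ILC3 cytokines, ILC1 cytokines and cytotoxic effectors, ILC2 cytokines and effectors, reported TTP target transcripts, TTP family and other decay factors, immediate-early and AP-1 genes, heat-shock genes, NF-kB pathway and feedback genes, cytokine and chemokine receptors, ILC transcription factors, interferon-stimulated genes, MHC class II presentation, glycolysis and hypoxia genes, survival and checkpoint genes, JAK-STAT feedback genes, tissue residency and migration genes, neuropeptide receptors and genes, and cycling genes. Genes were also grouped by the number of TATTTAT motifs, the core of the sequence bound by TTP, in the longest annotated 3 prime UTR.

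Genes are named by a rule: Zfp36 and its paralogs Zfp36l1 and Zfp36l2; for each class and for all kept cells, the 10 higher and 10 lower genes whose interval lies farthest from 0, leaving out mitochondrial, ribosomal, immunoglobulin, sex-linked and unnamed gene models; list members counted as higher or lower whose interval excludes 0; and always the main ILC cytokines and lineage regulators, among them Tbx21 and Gata3. Some genes that the rule names are not reported here. The lists, comparisons, named-gene rule and most alternatives were fixed before the data were examined. Alternatives covered clustering resolution, variable genes, centring within libraries, cell filters, naming per cell, scaling, UMI minimum, equal weight per cell, thinning depth and motif. Added after the data had been seen were shares among the ILC classes, cells of female type (at least 1 Xist UMI and no Y-linked UMI), Il22 without the 5% of cells richest in it, clustering without the genes of all lists and Ly6a, and ratios with the CPM of each knockout cluster weighted by the WT share of UMIs of that cluster. Work was done in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.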

Results

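The data are 2 single-cell RNA libraries of sorted small-intestinal lamina propria ILCs, 1 from a pool of 4 WT mice and 1 from a pool of 4 Zfp36_KO mice. Zfp36 encodes tristetraprolin (TTP), an RNA-binding protein that promotes decay of transcripts with AU-rich elements, many of them cytokine transcripts. The WT library held 3593 barcodes and 24721524 UMIs, and the knockout library 3522 barcodes and 27733804 UMIs. After filtering, 3352 WT cells with a median of 5291 UMIs and 3302 knockout cells with a median of 5319.5 UMIs were kept. There were no replicate libraries, and each mouse pool is a single measurement. Sex-linked transcripts differed between the pools: 447 knockout cells (13.5%) had Y-linked UMIs without Xist, against 0 in WT.

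The first comparison asked which ILC classes made up the sorted cells of each genotype, since the study concerns an expansion of IL-22-producing ILCs without TTP. ILC2-like cells took 16.2% (95% interval 14.97 to 17.49) of kept WT cells and 31.1% (29.5 to 32.7) of kept knockout cells. ILC3-like cells, the main source of IL-22 in the gut, took 29.8% (28.3 to 31.4) in WT and 34.1% (32.5 to 35.8) in knockout. ILC1/NK-like cells took 4.95% (4.24 to 5.74) and 4.15% (3.49 to 4.89), with overlapping intervals, but 10.4% (9.40 to 11.5) and 12.9% (11.8 to 14.1) with the unnamed cluster 5 counted among them, so the direction of this share depends on the naming. The ILC2-like difference was 14.9 points, and 9.53 points when genes were centred within each library. Although the sort gate excluded CD3+ and TCRβ+ cells, T-cell-like cells made up 29.2% (27.7 to 30.8) of WT cells and 0.727% (0.466 to 1.08) of knockout cells. Among the 3 ILC classes alone, the ILC3-like share was lower in the knockout library, at 49.2% (47.1 to 51.3) against 58.5% (56.1 to 60.8) in WT, while the ILC2-like share was again higher, at 44.8% against 31.8%.

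Within ILC3-like cells, LTi-like clusters held 61.5% (58.4 to 64.5) of WT and 67.6% (64.8 to 70.3) of knockout cells, and the NCR+ cluster held the rest. The direction of this difference is not settled. It turned under naming of single cells and under a finer clustering, where LTi-like and NCR+ shares were both lower in knockout, while 28.5% of WT and 43.9% of knockout ILC3-like cells had no subset name. The LTi-like cells lay in different clusters in the 2 libraries. Cluster 2 held 292 WT and 692 knockout cells, cluster 7, with the highest level of the LTi marker Ccr6, held 322 WT and 70 knockout cells, and the NCR+ cluster 3 held 385 and 365. The ILC2-like cells came from cluster 1 (328 WT and 761 knockout cells), cluster 6 (184 and 254) and cluster 18 (31 and 11). ILC1/NK-like cells formed cluster 8.

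**Figure D1:**
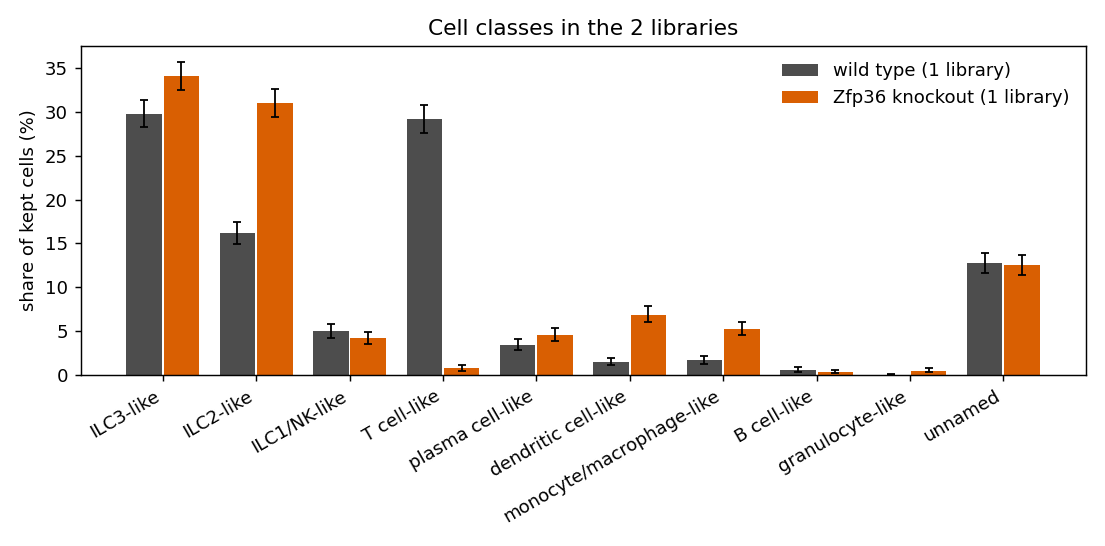
Share of kept cells (percent) in each cell class for the WT and the Zfp36_KO library, with exact binomial 95% intervals as bars. ILC2-like cells were at 16.2% in WT and 31.1% in knockout, and T-cell-like cells at 29.2% and 0.727%.

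Zfp36 (ENSMUSG00000044786; mm10 chromosome 7, 28376784 to 28380253, minus strand) was lower in each ILC class of the knockout library. In ILC3-like cells it had 5590 UMIs in WT and 1459 in knockout, a log2 ratio of -1.92, or 3.79-fold lower (3.57 to 4.01). The ratio was -1.24 (-1.33 to -1.16) in ILC2-like cells (-0.71 with knockout clusters reweighted to WT shares) and -1.88 (-2.15 to -1.62) in ILC1/NK-like cells. At equal depth, 68.2% of WT and 32.5% of knockout ILC3-like cells had a Zfp36 UMI. The tags come from the 3 prime end and the site of the targeted change is not given, so remaining tags do not show that protein was made. The paralog Zfp36l1 had a log2 ratio of -0.42 (-0.46 to -0.37) in ILC3-like and -0.25 (-0.29 to -0.20) in ILC2-like cells. Zfp36l2 stood at -0.12 in ILC3-like cells (0.17, 0.03 to 0.31, in LTi-like and -0.57, -0.75 to -0.39, in NCR+ cells) and at 0.20 in ILC2-like cells.

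The central comparison asked whether ILC3-like cells without TTP carry more Il22 transcript. Il22 (ENSMUSG00000074695; chromosome 10, 118204942 to 118210047, plus strand) was 2.19-fold higher (2.13 to 2.26) in knockout ILC3-like cells, at 3084 CPM against 1408 CPM. Its log2 ratio was 1.13 (1.09 to 1.17). By cluster, the log2 ratio was 1.49 in cluster 2, 0.96 in cluster 7 and 0.39 in the NCR+ cluster 3. Much of the transcript sat in few cells: the 5% of ILC3-like cells with the most Il22 UMIs held 60.8% of them in WT (50 cells) and 73.3% in knockout (57 cells). Without those cells the log2 ratio was 0.59 (0.52 to 0.66).

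Over all ILC3-like cells, the share with an Il22 UMI differed less than the transcript level. At 2000 UMIs per cell it was 28.0% (25.2 to 30.9) in WT and 33.2% (30.4 to 36.1) in knockout. ILC2-like cells, which should lack Il22, gave a background of 0.558% and 1.10%. The median depths before thinning were 4518 and 3752 UMIs in ILC3-like cells and 6243 and 5777.5 in ILC2-like cells. LTi-like cells gave 29.6% and 32.2%, and NCR+ cells 26.7% (22.3 to 31.5) and 35.5% (30.5 to 40.7), with overlapping intervals in both subsets. In NCR+ cells the share and the level (1.31-fold) differed about alike, with 2876 CPM in WT and 2897 CPM in knockout as the mean of the cells with a UMI. At least 10 Il22 UMIs at that depth were found in 84 of 972 WT and 118 of 1069 knockout ILC3-like cells. Before thinning, the median level of ILC3-like cells with an Il22 UMI was 1289 CPM in WT and 1253 CPM in knockout. Their mean was 4010 and 6963 CPM, so much of the higher level lay in the richest cells. Not all of it did, since Il22 stayed higher in knockout without the 5% of cells richest in it. The median of all ILC3-like cells with a UMI was not higher. The medians were 2043 and 1871 CPM in LTi-like and 697 and 856 CPM in NCR+ cells.

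Other ILC3 cytokines went in both directions. Il17f was 4.29-fold higher (3.21 to 5.82; log2 ratio 2.10, or 1.05 with knockout clusters reweighted to WT shares), found in 24 WT and 41 knockout cells. Il17a had 1 UMI in WT and 63 in knockout, of which 35 came from 1 cell. Csf2 (ENSMUSG00000018916; chromosome 11, 54247271 to 54249667, minus strand), encoding GM-CSF, was 3.22-fold lower (2.94 to 3.54). Lymphotoxin beta (Ltb) had a log2 ratio of -0.71 (-0.77 to -0.66), Tnf -0.45 (-0.63 to -0.28; 0.62 in LTi-like and -0.79 in NCR+ cells) and Ifng -1.47 (-1.92 to -1.04). Il13 had 2 UMIs in each library and Il5 had 0. Among lineage regulators, Gata3 stood at -0.10 (-0.26 to 0.06) and Tbx21 at -1.04 (-1.42 to -0.66).

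**Figure D2:**
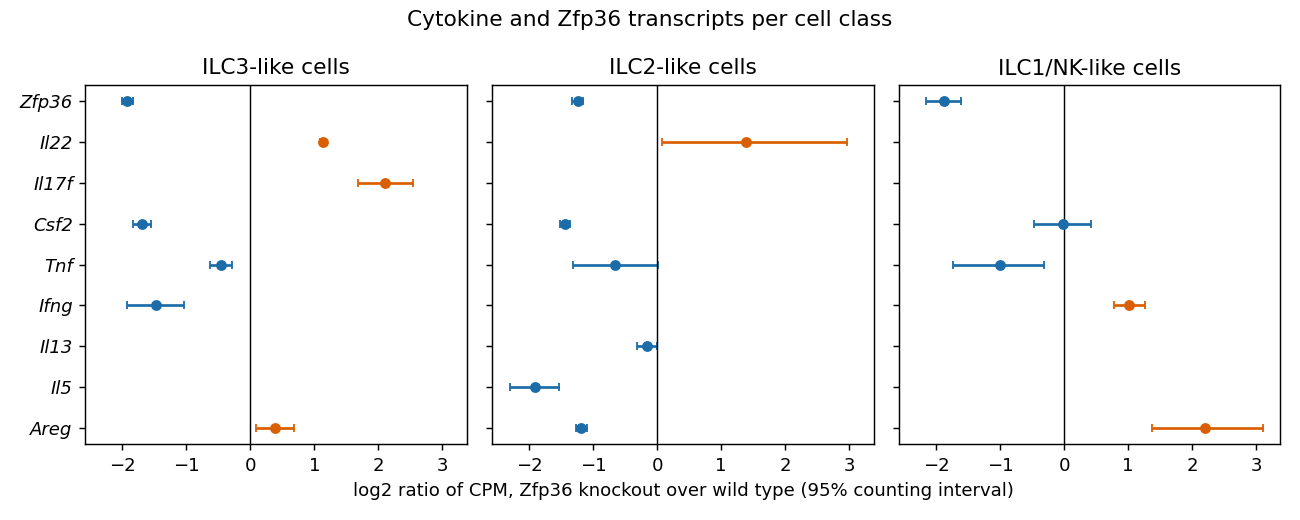
Log2 ratio of CPM, knockout over WT (1 library each), of Zfp36 and 8 cytokine transcripts in each ILC class, with 95% counting intervals as bars, for genes with at least 20 UMIs and none at 0 in either library. In ILC3-like cells Il22 stood at 1.13 and Csf2 at -1.69.

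Beyond cytokines, Ly6a came first among the genes higher in ILC3-like knockout cells when ranked by the end of the interval nearest 0. It encodes the interferon-inducible surface protein Sca-1. Ly6a (ENSMUSG00000075602; chromosome 15, 74994877 to 74998031, minus strand) was 32.5-fold higher (23.7 to 46.0), and at equal depth 25.4% of knockout against 1.65% of WT ILC3-like cells had a UMI. With all deposited barcodes its log2 ratio was 3.72 instead of 5.02. Plac8 was 7.93-fold higher, Palld 7.80-fold, Pou2f2 5.24-fold, Alcam 4.95-fold and the interferon-induced GTPase Tgtp2 4.37-fold. Serpinb8 and Heyl also belonged to the 10 named higher genes, at log2 ratios of 3.92 and 2.76. Ifitm1 did as well, but 93 of its 110 knockout UMIs came from 1 cell. Lower genes were Piwil4 (6.98-fold), which marks the WT-rich cluster 7 and stood at -1.21 instead of -2.80 with knockout clusters reweighted to their WT shares, Pcp4 (5.08-fold), AY036118 (8.43-fold), Nrg2, Hebp1 and Cldn10. The lower genes S100g, Ccl3 and Cxcl1 rested on 26, 23 and 5 WT cells. The activation marker gene Cd83, Icam1 and the lymphotactin gene Xcl1 stood at -1.33 (-0.08 reweighted), -1.52 and -1.94, whereas Pdcd1, Zeb2 and the IL-23 receptor gene Il23r stood at 2.02, 1.77 and 0.78.

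Of 9522 genes measured in ILC3-like cells, 277 were at least 2-fold higher and 103 at least 2-fold lower in knockout. The median of all genes was 0.17 above 0, with ribosomal protein genes lower (90 of 98, median -0.38) in the knockout library. Relative to that median, 140 genes were higher and 168 lower, and the log2 ratio of Il22 was 0.96. With a minimum of 200 UMIs per gene, 107 were higher and 40 lower. In ILC2-like cells the counts were 300 higher and 98 lower of 8883, or 161 and 151 relative to a median of 0.17. ILC1/NK-like cells gave 177 and 61 of 4656, or 112 and 85 relative to a median of 0.12.

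ILC2-like cells, producers of type 2 cytokines, differed most in Gzma, the gene of the serine protease granzyme A. Gzma (ENSMUSG00000023132; chromosome 13, 113093825 to 113100981, minus strand) had 32 UMIs in WT and 12971 in knockout, 245-fold higher (174 to 359). At equal depth 33.1% (30.2 to 36.1) of knockout and 0.743% (0.203 to 1.89) of WT ILC2-like cells had a Gzma UMI. ILC3-like cells gave 0.842% and 1.13%. Several effector transcripts were lower: Il5 had a log2 ratio of -1.91 (-2.30 to -1.53), Areg, encoding the epithelial repair factor amphiregulin, -1.19 (-1.27 to -1.10), and Csf2 -1.44 (-1.51 to -1.36). Il4 stood at -0.61 (-0.72 to -0.50) and Il13 at -0.16 (-0.31 to -0.01), and the direction of Il13 was lost when each cell had equal weight. Cluster 6, whose most enriched genes included Areg, Csf2 and Il13, held 184 of 543 WT and 254 of 1026 knockout ILC2-like cells.

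Further genes higher in knockout ILC2-like cells were Scin (17.2-fold), Neb (5.62-fold), Slc15a2 (5.75-fold), Scel, Hs6st2 and the interferon-induced GTPases Iigp1 (4.77-fold), Tgtp2 (4.45-fold) and Gbp10. H2-Aa, an MHC class II chain, was 5.71-fold higher (4.46 to 7.42). Lower were Lgals1 (22.0-fold), Ctla4 (7.05-fold), Mapk12, Bcl2a1d, S100a6, S100a4, Rgcc, Stab2 and the chemokine genes Cxcl2 and Ccl1. Lgals1 rested on 41 WT and 8 knockout cells, Ctla4 on 36 and 8, and S100a6 on 41 and 34. A single WT cell held 43.1% of the Ccl1 UMIs. Ccl1, Rgcc, S100a4 and the alarmin receptor gene Il1rl1 (ST2) mark cluster 18, which held 31 WT and 11 knockout cells. Il1rl1 stood at -1.04 (-1.30 to -0.78), but at 0.0197 (-0.28 to 0.30) with knockout clusters reweighted to WT shares. Genes such as Il1rl1 were not left out of the clustering and could help to form these clusters. The reweighting therefore cannot tell a difference in expression from one in cluster shares. The same limit holds for S100a4, at -0.59 instead of -2.25, S100a6, at -0.60 instead of -2.36, Rgcc, at -0.98 instead of -2.10, and Ccl1, at -2.44 instead of -3.42. The IL-25 receptor gene Il17rb, a marker of cluster 1, stood at 0.68 (0.59 to 0.76) and at 0.61 reweighted.

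ILC1/NK-like cells were few, with 166 in WT and 137 in knockout. Ifng, the main ILC1 cytokine, had 247 and 354 UMIs, a log2 ratio of 1.02 (0.78 to 1.26), or 0.68 in cells of female type, but 21.8% and 23.5% of cells had a UMI at equal depth, and 33.6% of the WT UMIs came from 1 cell. Ly6a was 9.04-fold higher, found in 10 WT and 44 knockout cells, Plac8 4.77-fold, Gas7 4.50-fold, Arrdc4 3.57-fold, Pecam1 3.23-fold and the proprotein convertase gene Furin 2.69-fold. Golga3 was higher as well. Ifitm1, Cxcl10 and Areg were higher too, but with 29.4% of the knockout Cxcl10 UMIs and 48.1% of the knockout Areg UMIs in 1 cell. Chemokine genes Ccl3 and Ccl5 were lower, at -1.35 (-1.56 to -1.13) and -0.93 (-1.03 to -0.83). With cluster 5 counted in this class, Ccl3 stood at -0.69, Ccl5 at -0.15, Ly6a at 0.66 (against 3.18), Zfp36 at -0.93 and Ifng at 0.80. Also lower were AY036118, Ltb4r1, Rhob, Tspan32, Hspa1a, Klf2, Serpinb1a and Cks2. Csf2 stood at -0.02 (-0.46 to 0.41).

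**Figure D3:**
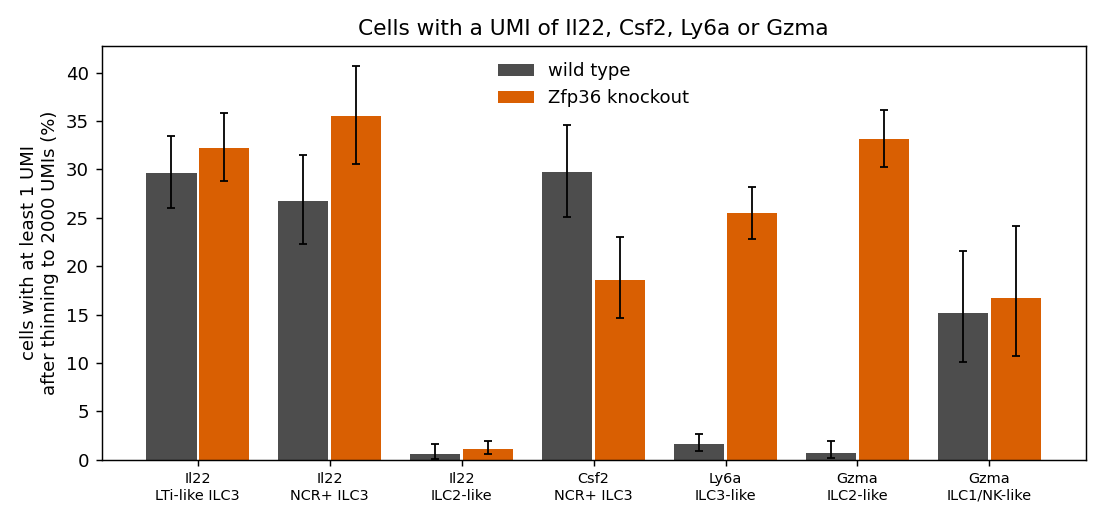
Share of cells (percent) with at least 1 UMI of Il22, Csf2, Ly6a or Gzma after thinning to 2000 UMIs per cell, in the named ILC class or ILC3 subset of the WT and Zfp36_KO libraries, with exact binomial 95% intervals as error bars. Gzma in ILC2-like cells stood at 0.743% in WT and 33.1% in knockout, and Il22 in NCR+ ILC3-like cells at 26.7% and 35.5%.

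Over all kept cells, the ratios mix the kinds of cells present with the expression in them, and these were not separated. The genes highest over WT included the myeloid cell genes S100a9 and Chil3, at 0 UMIs in WT (at least 62.0-fold and 75.0-fold higher), and Ccl24, at 29 UMIs in WT and 821 in knockout. Those lowest included the T cell genes Trac (6975 UMIs in WT and 120 in knockout), Cd5, Gzmk, Tnfrsf4 and Il21. Of 12170 genes, 1014 were at least 2-fold higher and 406 lower. Zfp36 was also lower, and Il22 was 1.92-fold higher (1.86 to 1.97).

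Transcripts reported as TTP targets were not higher as a group in the named ILC classes. In ILC3-like cells 8 of 30 measured were higher, among them Il22, Il17f, Vegfa and Hif1a, and 9 were lower, among them Csf2, Ifng, Junb, Nfkbid and Zfp36 itself. Their median of -0.23 lay at percentile 0.02 of matched random lists, and in cells of female type it was -0.15 (percentile 0.875). In NCR+ cells 0 of 26 were higher and 10 lower (median -0.38, percentile 0), and in LTi-like cells 8 of 23 were higher and 6 lower (median -0.13, percentile 5.01, within random lists). The difference between the subsets was not tested, here or for the other lists. In ILC2-like cells 7 of 25 were higher and 10 lower (median -0.25, percentile 0.025), and in ILC1/NK-like cells 3 of 19 were higher and 7 lower (median -0.35, percentile 0.19). The interferon-stimulated list lay high in ILC2-like, ILC1/NK-like and LTi-like cells. Its median was 0.28 in ILC3-like cells (8 of 21 higher and 2 lower, percentile 85.7, within random lists), 0.55 in their LTi-like subset (9 of 19 higher and 0 lower, percentile 99.8), 0.27 in their NCR+ subset (3 higher and 3 lower, percentile 78.9), 0.44 in ILC2-like cells (8 of 21 higher and 1 lower, percentile 99.5) and 0.59 in ILC1/NK-like cells (11 of 21 higher and 0 lower, percentile 99.95, but 87.4 with cluster 5 included).

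MHC class II genes lay low in ILC3-like cells and high in ILC2-like and ILC1/NK-like cells. The direction in ILC3-like cells depended on how the clusters were weighted. In ILC3-like cells 5 of 8 were lower and 0 higher (median -0.62, percentile 0), and they lay low in both subsets (LTi-like: 6 of 8 lower, median -0.72, percentile 0.01; NCR+: 1 of 6 lower, median -0.30, percentile 0.9). Cd74 stood at -0.82 and H2-Eb1 at -0.98, and with knockout clusters reweighted to WT shares they turned to 0.50 and 0.42. Both are also among the markers that named LTi-like clusters, and MHC class II genes were not left out of the clustering. The reweighting also rests in part on the 70 knockout cells of cluster 7. NCR+ cells are the single cluster 3, so a shift between these clusters cannot account for the low values there. Macrophage markers in ILC3-like cells stood at 94.4 CPM in WT and 51.7 in knockout, B cell markers at 108 and 66.7, and dendritic cell markers at 47.7 and 36.1. In ILC2-like cells 6 of 7 were higher (median 1.19, percentile 100), with Cd74 at 1.12 and H2-Eb1 at 1.72 (1.07 and 1.63 reweighted), and in ILC1/NK-like cells 4 of 5 (median 0.84, percentile 99.7). The summed level of macrophage markers in ILC2-like cells was 21.7 CPM in WT and 22.4 CPM in knockout, and that of dendritic cell markers 6.58 and 3.15 CPM. In ILC1/NK-like cells macrophage markers stood at 68.7 and 48.6 CPM and dendritic cell markers at 56.5 and 86.2 CPM, so RNA of dendritic cells is not excluded as part of the MHC class II difference there. Immediate-early and AP-1 genes lay low against random lists in all 3 classes, at medians of -0.30 (6 of 22 lower), -0.41 (6 of 20) and -0.28 (6 of 19) in ILC3-like, ILC2-like and ILC1/NK-like cells. Among ILC3-like cells the NCR+ subset had 9 lower (median -0.55, percentile 0), and the LTi-like subset 3 lower (median -0.14, percentile 13.98, within random lists). Some members were higher, namely Egr2 and Ier3 in ILC3-like cells, Fos and Klf6 in ILC2-like cells and Nr4a3 in ILC1/NK-like cells. Of the 23 knockout UMIs of Ier3, 13 came from 1 cell. NF-kB feedback genes lay low in ILC3-like cells (median -0.22, percentile 0.19, Nfkbia at -0.76; 0.66 in LTi-like and 3.50 in NCR+ cells) and ILC2-like cells (median -0.32, percentile 0), and stood at percentile 36.2 in ILC1/NK-like cells.

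JAK-STAT feedback genes had medians of 0.35 (percentile 96.7), 0.32 (percentile 94.1) and 0.44 (percentile 99.5) in ILC3-like, ILC2-like and ILC1/NK-like cells, and lay high in both ILC3 subsets (percentile 98.0 in LTi-like and 98.3 in NCR+ cells). Pim2 and Stat3 were higher in each of these classes. ILC2 cytokines and effectors lay low in ILC2-like cells (5 of 9 lower, median -0.61, percentile 0). ILC3 cytokines in ILC3-like cells had 3 members higher and 3 lower of 10, with a median of -0.05 at percentile 15.7, but lay low in NCR+ cells (1 higher and 4 lower, median -0.47, percentile 0.02) and not in LTi-like cells (4 higher and 3 lower, percentile 52.9). ILC1 cytokines and cytotoxic effectors lay at percentile 17.9 in ILC1/NK-like cells, at 0.66 in ILC3-like cells and at 98.6 in ILC2-like cells. In the last, 3 of 5 measured members were higher, among them Gzma and Prf1, and Ccl5 was lower. Cytokine and chemokine receptors lay low in ILC2-like cells (3 of 20 higher and 9 lower, median -0.39, percentile 0) and at percentile 8.31 in ILC3-like cells. Of the lower members in ILC2-like cells, Il1rl1 and Il10ra did not keep their direction with knockout clusters reweighted to WT shares. Neuropeptide receptors and genes lay low in ILC3-like cells (median -0.51, percentile 0), with Ramp1 1.63-fold lower.

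For the other lists, the percentiles in ILC3-like cells were 63.6 for the TTP family and other decay factors, 57.2 for heat-shock genes, 84.3 for ILC transcription factors (98.7 in the LTi-like subset), 56.8 for glycolysis and hypoxia genes, 76.3 for survival and checkpoint genes, 3.34 for tissue residency and migration genes (2.34 in the NCR+ subset) and 13.4 for cycling genes. In ILC2-like cells each of these 7 lists also lay within random lists. In ILC1/NK-like cells heat-shock genes lay low (median -0.27, percentile 2.21), and the other 6 within random lists.

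**Figure D4:**
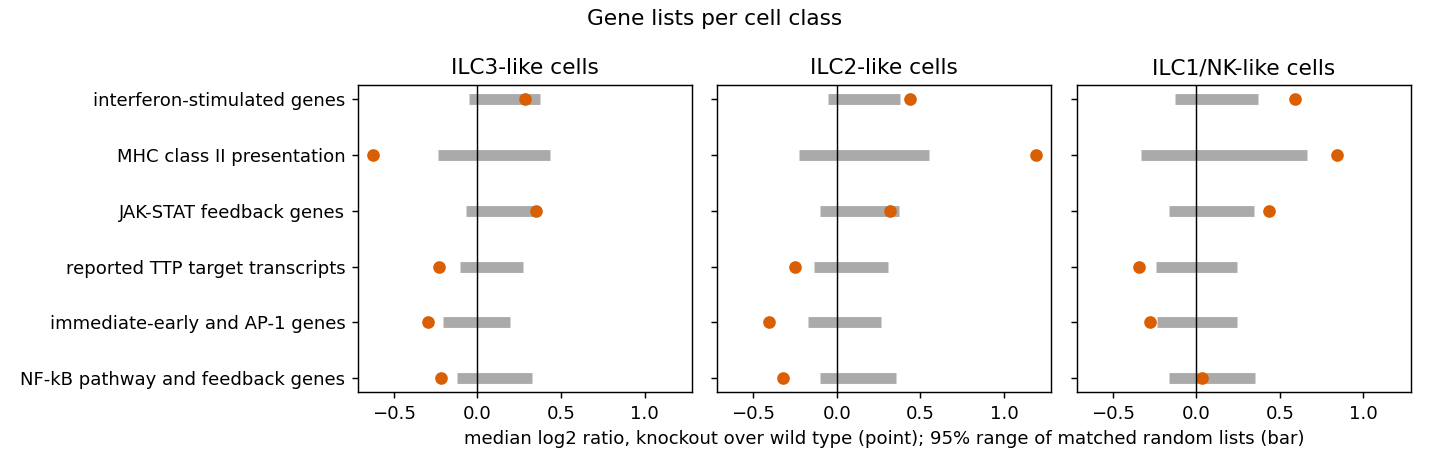
Median log2 ratio, knockout over WT, of 6 of the 18 gene lists in ILC3-like, ILC2-like and ILC1/NK-like cells (points), beside the central 95% of the medians of matched random lists (grey bars). MHC class II genes stood at -0.62 in ILC3-like and 1.19 in ILC2-like cells.

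The last comparison asked whether transcripts with the TTP motif in their annotated 3 prime UTR were higher without TTP. In ILC3-like cells the 1040 genes with 2 or more TATTTAT motifs had a median log2 ratio of 0.30, above each matched random list (median 0.17, percentile 100). Genes with 1 motif had a median of 0.26, and the 6384 genes with none 0.12. Matching on UTR length as well raised the random median to 0.28 (percentile 98.2). The percentile was also 100 in ILC2-like cells (967 genes, median 0.33) and in ILC1/NK-like cells (509 genes, median 0.32). Il22 and Ifng carry 4 of these motifs, Il17f 2 and Csf2, which was lower, 9, whereas Gzma and Ly6a carry 0.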

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

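The tests of T cell doublets, free T cell RNA and sort purity, and that of a shift between ILC3-like clusters, were chosen only after the results were seen, and the division by sex was added after the data had been seen.

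Il22 was higher in knockout ILC3-like cells, at a log2 ratio of 1.13. The male cells of the knockout pool do not account for it, since the ratio was 0.99 in cells of female type, although male-type knockout cells had more Il22 (6130 CPM) than those of female type (2787 CPM). A shift between the LTi-like and NCR+ clusters, as divided here, does not account for it either. With knockout values reweighted to WT subset shares the ratio was 1.09, and 0.95 over the 3 ILC3-like clusters. Il22 was left out of the clustering, but other divisions of the ILC3-like cells were not reweighted, so shifts within these clusters are not excluded. Transcripts with 2 or more TTP motifs were higher as a group, at percentile 100 of matched random lists. Their median exceeded that of random lists by only 0.13, and by 0.02 when UTR length was matched, sizes looked at after the percentile. Slower decay without TTP would raise such transcripts, but the reported TTP targets lay low as a group in ILC3-like cells (median -0.23, percentile 0.02). In the LTi-like subset they lay within random lists (percentile 5.01). Their list includes Zfp36 itself, which the knockout lowers, and shares members such as Junb and Nfkbid with the immediate-early and NF-kB lists. It was not run without these genes. Csf2 with 9 motifs was lower. The excess of the motif group is small beside the Il22 difference and may add to it, but it does not measure how TTP acts on Il22 itself. The part of the genotype remains untested with 1 library each.

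Gzma was 245-fold higher in knockout ILC2-like cells. Male cells in the knockout pool do not account for it, since the log2 ratio in cells of female type was 7.89. RNA or cells of cytotoxic lymphocytes do not account for it: Nkg7, Ccl5 and Gzmb reached 0.0895, 0.000967 and 0.00834 (the median) of the level that Gzma would imply from the cytotoxic cells of the same library. The ratio in male knockout cells was 8.23, so both sexes showed it, but the knockout genotype cannot be told apart from the library, because each genotype was 1 library. A gain of Gzma in ILC2-like cells without TTP is thus a hypothesis, and Gzma has no TATTTAT motif of its own.

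T-cell-like cells made up 29.2% of kept WT cells (27.7 to 30.8), a population outside the sorted ILCs that no comparison concerned. Doublets with ILCs do not account for them, since their median UMI count was 0.971 of that of ILC-like WT cells (0.945 to 0.996). Free T cell RNA would reach the ILC3-like cells of the same library as well. Cd3e, Cd3g and Trac stood 166-fold, 92.5-fold (the median) and 57.9-fold above their levels in those cells. All 3 belong to the marker list that named the T-cell-like clusters, so high ratios were partly set in advance and cannot decide this. Trac, as an antigen receptor gene, was left out of the clustering itself. A difference in sort purity, judged by that share of 29.2% in WT, cannot be told apart from an effect of genotype on T cells with low surface CD3 or TCRβ, since each genotype was sorted and sequenced as 1 pool. Shares of all kept cells depend on it, as the ILC3-like share shows.

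Ifng had a log2 ratio of 1.02 in ILC1/NK-like cells and of -1.47 in ILC3-like cells, opposite directions whose difference was not tested. Areg likewise stood at 2.20 in ILC1/NK-like cells, where it was found in 7 WT and 5 knockout cells, and at -1.19 in ILC2-like cells, and this difference was not tested. Kept knockout cells held 1339 Y-linked UMIs, a signal outside the comparisons, against 4 in WT. Dendritic-cell-like cells made up 6.87% (6.03 to 7.79) of knockout cells and 1.49% of WT cells, outside the sorted population. Monocyte- and macrophage-like cells made up 5.24% (4.50 to 6.05) of knockout cells and 1.67% of WT cells.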

How the results depend on the processing

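Shares among the 3 ILC classes, cells of female type, Il22 without its richest cells, cluster 5 counted as ILC1/NK-like, clustering without the genes of all lists and Ly6a, and knockout clusters reweighted to WT shares were tried only after the data had been seen. Of the main results, 150 values kept their direction and stayed within counting error (counts of genes within 1.5-fold), 36 moved, 3 reversed and 2 lost their call, and of the values for single genes and list members 317 stayed, 89 moved and 9 reversed. Unless the setting itself fixes the outcome, the cause was not tested. At resolution 2 the knockout minus WT difference was -2.38 points for ILC1/NK-like, -25.2 for T-cell-like and, reversed, -9.50 for LTi-like cells, where 28.5% of WT and 43.9% of knockout ILC3-like cells had no subset name and the NCR+ share was also lower (37.8% and 31.8%). Naming single cells gave -2.07 points for ILC1/NK-like and, reversed, -1.93 for LTi-like cells. Using all variable genes gave 18.0 points for ILC2-like cells, and centring within libraries 9.53, which left 374 knockout and 6 WT ILC3-like cells without a subset name. With cluster 5 counted as ILC1/NK-like, the difference for that class was 2.49 points instead of -0.80, a change of sign counted as moved because the interval of the latter held 0, and interferon-stimulated genes in it lay at percentile 87.4, no longer apart from random lists. Without the genes of all lists and Ly6a in the clustering, the difference was -25.5 points for T-cell-like cells, 6.92 for LTi-like and 14.7 for ILC2-like cells. Among the 3 ILC classes the difference was -3.74 points for ILC1/NK-like and, reversed, -9.28 for ILC3-like cells, since T-cell-like cells then leave the denominator. The log2 ratio of Il22 in ILC3-like cells was 0.96 with median-ratio scaling, 1.06 without mitochondrial and ribosomal protein genes, 0.97 with equal weight per cell, 1.09 with all barcodes, 0.99 in cells of female type, 0.95 with knockout clusters reweighted to WT shares and 0.59 without the 5% of cells richest in Il22. That of Il13 in ILC2-like cells reversed to 0.00912 with equal weight per cell. Reweighted to WT cluster shares, the ratios of H2-Aa, H2-Ab1, H2-Eb1, H2-DMb1 and Cd74 in ILC3-like cells reversed to 0.49, 0.32, 0.42, 0.15 and 0.50, and those of Atf3, Il1rl1 and Il10ra in ILC2-like cells to 0.28, 0.0197 and 0.0545.

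With median-ratio scaling, which moves all genes by the median shift, 140 genes were 2-fold higher and 168 lower in ILC3-like, 161 and 151 in ILC2-like, and 112 higher in ILC1/NK-like cells. A minimum of 20 UMIs, which admits more thinly counted genes, gave 442 and 201 in ILC3-like, 465 and 198 in ILC2-like, and 391 and 217 in ILC1/NK-like cells, and 648 lower over all kept cells. A minimum of 200 UMIs gave 107 and 40, 131 and 44, and 21 and 12 in these classes, and 200 lower over all kept cells. The difference in ILC2-like cells with Gzma was 28.7 points at 1000 UMIs per cell and 27.9 points for at least 2 UMIs. With the longer motif TTATTTATT, the percentile in ILC1/NK-like cells was 75.1, no longer apart from random lists, on fewer genes. The number of cells (166 and 137), not the depth per cell (median 5055.5 and 4524 UMIs), limits ILC1/NK-like cells, where 4656 genes reached 50 UMIs against 9522 in ILC3-like cells. No paired analysis was possible because each genotype was a single pool.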

Other observations

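The test of interferon-stimulated genes in ILC2-like and ILC1/NK-like cells was chosen only after the result was seen, the division by sex was added after the data had been seen, and cluster 5 was chosen after its values were seen. Cluster 5, with 183 WT and 289 knockout cells (5.46% and 8.75%), had 7 passing ILC1/NK and 6 passing ILC2 markers, but 0 and 1 of them among its 10 most enriched genes, and was given no class. Of its 9 measured ILC1 cytokines and cytotoxic effectors, 9 were higher in knockout (median log2 ratio 1.19, percentile 100), with Gzma at 6 UMIs in WT and 472 in knockout, Ccl5 at 1.58, Ccl4 at 1.36, Xcl1 at 1.19 and Ifng at 0.76. This differs in direction from Ccl3 and Ccl5 in ILC1/NK-like cells, a difference that was not tested. Zfp36 stood at -0.67 (-0.81 to -0.54) in this cluster. Reported TTP targets lay at percentile 99.6 there, with Tnfaip3 and Bhlhe40 among the 7 of 19 that were higher, and 4 of 5 MHC class II genes were higher.

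Cells outside the ILC classes also differed between the libraries. Cluster 10, a dendritic-cell-like cluster whose enriched genes included Plet1, Il22ra2 (the soluble IL-22 binding protein) and Csf2rb, held 30 WT and 178 knockout cells. Macrophage-like cluster 13, with C1qa and Csf1r, held 22 and 137 cells. Granulocyte-like cells numbered 0 of 3352 in WT, which allows a share of up to 0.110%, and 15 in knockout. T-cell-like cells of WT fell into cluster 4 (559 cells), a Trdc+ cluster 11 with Il17a (154 cells) and a Foxp3+ cluster 15 (133 cells), among others. Cluster 12, with Cd8a, Gzmb and killer receptor genes, held 149 WT and 15 knockout cells and was left unnamed, as T cell and NK markers competed in it.

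A hypothesis was that variants of another strain, carried along with the targeted Zfp36 allele, set some genes apart. Within 10 Mb of Zfp36, 9 of 165 genes (5.45%) were at least 2-fold apart in ILC3-like cells, against 370 of 9354 (3.96%) elsewhere, a ratio of 1.38 (0.638 to 2.55), so the count of genes was too small to decide. A second hypothesis was that male cells raised the interferon-stimulated genes of the knockout library. The median of the list in ILC3-like cells of female type was 0.32 against 0.28 in all ILC3-like cells, 1.13 of it, but the list lay within random lists there, so this decides nothing. Where it lay high, the median in cells of female type was 0.968 (0.743 to 1.40) of that in all ILC2-like cells and 0.859 (0.632 to 1.55) of that in all ILC1/NK-like cells. Most of the difference was thus present without male cells, and a smaller part from them stays open.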
